A study of Ovis aries with 8 samples.

How the data were processed

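The series measured RNA in cultured pulmonary artery endothelial cells of near-term sheep fetuses (Ovis aries) with 1-colour expression arrays. There were 8 arrays, 4 of control cultures and 4 of cultures from fetuses with intrauterine growth restriction (IUGR). Groups were taken from the treatment label, which reads normothermic for control and hyperthermic for IUGR. Replicate numbers within each group only name the cultures and pair none of them. The titles give each culture its own animal identifier and its passage. Per the labels, cells were grown in DMEM with 10% fetal bovine serum, total RNA was extracted with Trizol, and biotinylated cRNA was prepared by a standard Affymetrix protocol.

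The deposited values are linear intensity values in 1 table of 15380 rows, with 1 row per gene symbol or NCBI gene number. That they are linear was read from the values, which ran from about 3 to 8705 with a long upper tail. How the authors corrected background, summarised probes and normalised the arrays is not given in the sources used here. The quantiles of the 8 arrays nearly coincide, with medians of 37.7 to 41.1 intensity units and 90th percentiles of 304 to 330, so the deposited intensity values were not normalised again in the main analysis. The table holds no detection calls, and the number of arrays limits the precision.

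Rows were named through an NCBI RefSeq gene table of assembly ARS-UI_Ramb_v3.0, used for names only. The name of 12809 rows was a symbol in that table and 51 matched a synonym in it. A further 1613 rows kept the name in the deposited table. Of the 907 rows named by a gene number, 109 matched a symbol, 638 matched an entry with no symbol and 160 had no match. The array's genome build is not given in the sources used here, so no coordinates are reported. The gene level held 14577 genes after 798 rows without a symbol were left out and 5 rows were merged, keeping for each gene the row with the highest mean.

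Values below the 10th percentile of all values, 5.89 intensity units or 2.56 on the log2 scale, were raised to it before log2 was taken. Differences of dim genes are therefore understated, and values at this floor have no order. IUGR was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no filter and no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. All 8 arrays entered 1 fit. The same test was run over all rows and over genes.

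There were 25 gene lists fixed before the data were examined, as were the tests and the rule for named genes. They covered endothelial, arterial and Notch, venous and lymphatic, smooth muscle, fibroblast, leukocyte, and epithelial and mesothelial markers. Further lists held NF-kB pathway components, NF-kB target and adhesion genes, angiogenic ligands and receptors, vascular tone, cell cycle, hypoxia, heat shock, unfolded protein and amino acid response, TGF-beta and BMP signalling, extracellular matrix, insulin and IGF axis, oxidative phosphorylation, antioxidant, interferon response, cholesterol synthesis and imprinted genes. Another list, sex-linked check genes, had no measured member. The remaining list was tested with the others and counted in the adjustment, and its result is not reported. The NF-kB lists were written knowing that the published study of these cells concerns NF-kB. The 24 lists with at least 5 measured members were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. A list score, the mean over members of the log2 value minus the gene's mean, was computed for each array and compared by an exact two-sided permutation test over the 70 assignments, whose smallest possible p is 0.0286. Principal components were computed on the centred log2 values of all rows.

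Named genes were chosen by this rule. Among genes past the threshold whose groups did not overlap and whose higher group mean was at or above the median gene, up to 10 of the largest rises and falls were taken. Each list gave up to 4 members with the smallest unadjusted p. IKBKB, RELA, NFKB1, ICAM1, VCAM1, KDR, NOS3, VEGFA, EDN1, PECAM1, CDH5 and VWF were named wherever measured, and IKBKB and VCAM1 matched no row. Genes from outside the rule are marked where they appear.

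The alternatives covered quantile normalization, median centring, rows above the median by mean, log2(value + 1), log2(value + 32), a trended or robust prior, array weights, passage as a covariate, the leading title number as a random block, the mean of rows per gene, other thresholds, and leaving out each array in turn. After the data were seen, more were added: leaving out IUGR replicates 2 and 4, leaving out these and control replicate 4, the endothelial marker score as a covariate, and a filter at the 95th percentile (3.44 on the log2 scale) of 126 olfactory receptor rows, taken as a background level. Lists called in a setting but not in the main analysis, and those still called with passage as a covariate, were tested again in that setting with an estimated correlation. The closing section gives their effect. The test was tried on 20 simulated data sets of 14577 genes with the observed means and spreads and 200 changed genes. It recovered 37.7% of genes changed by 1 log2 unit, 75.7% of those changed by 2 and 92.7% of those changed by 4, and 6.51% of its calls were genes left unchanged. Each simulated gene was drawn independently of the others. The simulation therefore lacks the correlation between genes and the sample structure of these arrays, and its rates may not hold for them. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.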

Results

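Gene expression was measured in pulmonary artery endothelial cells, the cells that line the arteries carrying blood from the heart to the lungs, cultured from near-term fetal sheep. There were 4 control cultures and 4 cultures from growth-restricted (IUGR) fetuses, labelled hyperthermic, and each culture was measured on 1 array. Values are log2 intensities unless a percentage or fold is named, and each ± is a standard deviation over the 4 arrays of a group. Control cultures were at passage 5 or 6 and IUGR cultures at passage 3 or 4, so passage did not overlap between the groups. The comparison addressed how gene expression in these cells differs with growth restriction. All 4 IUGR cultures carried the hyperthermic label and all 4 controls the normothermic one. Growth restriction and hyperthermia therefore cannot be told apart, and neither can be told apart from passage.

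The gene for the endothelin A receptor, EDNRA, rose from 3.52 ± 0.19 in control to 6.15 ± 0.45 in IUGR cultures (n = 4 each). Its control values, 3.27 to 3.71, lay around the olfactory receptor level of 3.44 taken as background. F3, tissue factor, the starter of blood coagulation, rose from 2.66 ± 0.15, near the floor, to 7.53 ± 1.06. PCDH1, a protocadherin adhesion molecule, fell from 8.86 ± 0.68 to 5.11 ± 0.50, which is 13.5-fold lower on the linear scale. The scaffold gene TANC1 fell by 1.42 ± 0.14 (SE), the cytoskeletal PDZ and LIM gene PDLIM1 fell by 1.06 ± 0.10 (SE), and DTWD1 rose by 0.90 ± 0.09 (SE).

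These were among 10 of 14577 genes that passed in the limma test, 6 higher and 4 lower in IUGR, all at an adjusted p of 0.0443. The other 4 lay below the median gene and were named after their values were seen: PHACTR1, OSCP1 and CASC1 rose by 1.57, 0.91 and 0.62, and MYOZ3 fell by 0.87. CASC1 lay below the olfactory receptor level of 3.44 on every array, at 2.56 to 2.64 in control and 3.11 to 3.29 in IUGR. Its call therefore rests on values at background in both groups. PHACTR1 was 3.77 in control replicate 4 and below that level in the other controls, at 3.08 to 3.19. At the row level limma called 0 of 15380 rows, with a smallest adjusted p of 0.0517, although 2350 rows had an unadjusted p under 0.05. At the gene level 2315 genes (15.9%) did, 1195 higher and 1120 lower, against 729 expected by chance; after quantile normalization the directions were 1028 and 1354, and after median centring 1028 and 1355. The groups did not overlap for 1261 genes (8.65%, with 2.86% expected by chance). Leaving out control replicate 4 gave 369 genes, 200 higher and 169 lower, while leaving out any other single array left 0 to 3. No gene passed with passage or with the endothelial marker score as a covariate, after median centring, with log2(value + 32) or with a robust prior. Some other settings called more, with 19 genes after quantile normalization and 74 with array weights.

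Control replicates 1 to 3 lay together, apart from every other array. Their log2 values correlated at 0.965 to 0.976 across rows, which are not independent. Control replicate 4 correlated with them at 0.917 to 0.922 and with IUGR replicates 1 and 3 at 0.957 and 0.955. The first principal component held 44.9% of the variance. Its scores were -42.9 ± 30.3 in control and 42.9 ± 24.9 in IUGR (exact two-sided permutation p = 0.0286, the smallest the design allows), with control replicate 4 at 2.56 and the other controls between -59.8 and -56.4. The second held 25.3% and its group means differed by 0.69 (exact permutation p = 0.943). IUGR replicates 2 and 4 had scores of 22.6 and 60.3 on it, and IUGR replicates 1 and 3 had -51.6 and -29.9.

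**Figure D1:**
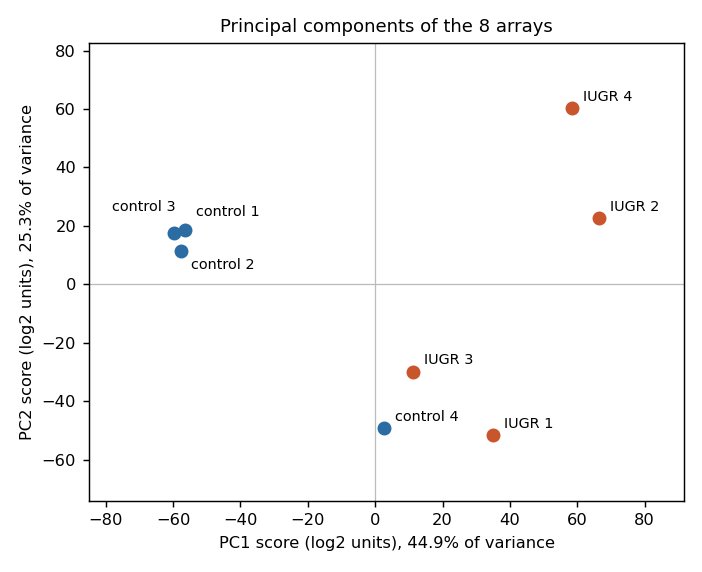
Scores of the 8 arrays on the first (horizontal) and second (vertical) principal component of the log2 values, in log2 units. Blue points are control and orange points IUGR cultures. Control replicates 1 to 3 sit between -59.8 and -56.4 on the first component, and control replicate 4 sits at 2.56.

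Endothelial markers had lower values in IUGR cultures for 20 of the 21 measured. PECAM1, a junction protein of endothelial cells, was 10.89 ± 0.87 in control and 6.02 ± 3.05 in IUGR, CDH5, the VE-cadherin gene, was 10.43 ± 0.82 and 5.87 ± 3.21, and KDR, the main VEGF receptor, was 9.00 ± 1.47 and 5.01 ± 2.74. The most regular differences were those of MMRN2, at -1.29 ± 0.22 (SE), and ROBO4, at -2.68 ± 0.53 (SE). ESAM, TAL1, NOS3 and VWF differed by -4.09, -2.11, -2.05 and -1.54. No member passed over all genes, and 14 lower members passed when adjusted over the list alone. The list shifted lower in limma's camera test (adjusted p = 2.296e-09), but not with an estimated correlation (adjusted p = 0.667 with an estimated correlation), and its scores gave an exact permutation p of 0.0571. With passage as a covariate it still passed in camera (adjusted p = 1.637e-06, and adjusted p = 0.821 with an estimated correlation).

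The endothelial values varied between cultures. As a percentage of the mean of control replicates 1 to 3, the PECAM1 intensity was 30.6% in control replicate 4, 7.74% and 28.1% in IUGR replicates 1 and 3, and at most 0.384% and 0.479% in IUGR replicates 2 and 4, where its log2 values of 3.31 and 3.63 lay below and just above the olfactory receptor level of 3.44. Percentages of markers at that level are upper bounds. The median over the 21 markers was 37.1% in control replicate 4 and 17.9%, 3.96%, 47.3% and 3.04% in IUGR replicates 1 to 4. In IUGR replicates 2 and 4, 7 and 9 of the 21 were at or below the level of olfactory receptor rows, against 0 in each other array. Some markers, named here after their values were seen, went another way. PLVAP, an endothelial gene of fenestrae and caveolae, stood at 255% of the mean of control replicates 1 to 3 in control replicate 4 and at 379% in IUGR replicate 3, but at most at 1.78% and 2.13% in IUGR replicates 2 and 4. FLT1, a VEGF receptor, stood at 149%, 127% and 129%, and ENG, endoglin, at 106%, 84.8% and 136%, in control replicate 4 and IUGR replicates 1 and 3. PROCR, the protein C receptor, stood at 94.7% in IUGR replicate 2 and 223% in IUGR replicate 3. It was lower in the other arrays, at 57.3% in control replicate 4 and 72.0% and 54.5% in IUGR replicates 1 and 4.

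Fibroblast markers had higher group means in IUGR for all 18 measured members. The list scores overlapped between the groups, at 1.18 in control replicate 4 and 0.33 in IUGR replicate 4 (exact permutation p = 0.0571). DCN, a matrix proteoglycan, was 5.57 ± 2.52 in control and 10.74 ± 0.44 in IUGR cultures, and PDGFRA, the PDGF receptor of mesenchymal cells, was 3.84 ± 0.46 and 7.60 ± 1.66. MFAP4 differed by 3.15 ± 0.77 (SE). FAP was at the floor of 2.56 in control replicates 1 to 3, 8.76 in control replicate 4 and 9.52 ± 0.66 in IUGR. Over all genes no member passed and 5 did when adjusted over the list alone. Camera gave the list an adjusted p of 9.891e-06, and an adjusted p = 0.598 with an estimated correlation. With passage as a covariate the values were 0.00892, and adjusted p = 0.821 with an estimated correlation.

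The other marker lists gave no call. Of 18 smooth muscle markers 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.487), though the list passed as higher without control replicate 4 (adjusted p = 0.0139) or without IUGR replicate 4 (adjusted p = 0.0246). In these settings it did not pass with an estimated correlation (adjusted p = 0.720 and 0.789 with an estimated correlation). DES, the muscle filament desmin, was 4.72 ± 0.39 in control and 7.16 ± 1.81 in IUGR cultures. MCAM, also carried by endothelial cells, was 8.72 ± 0.24 and 5.68 ± 2.18. The smooth muscle scores were 1.63 in control replicate 4, 1.17, 0.55 and 0.70 in IUGR replicates 1 to 3, and between -1.33 and -0.72 in the other 4 arrays. Of the 15 epithelial and mesothelial markers 0 passed either way (camera adjusted p = 0.500), yet KRT18, a simple-epithelium keratin, was 9.06 and 11.04 in IUGR replicates 2 and 4 and at most 5.21 elsewhere. WT1, a mesothelial transcription factor, was 7.92 and 9.21 there and at most 3.20 elsewhere, and MSLN, mesothelin, was 9.49 and 8.71 there and at most 5.72 elsewhere. Of 11 venous and lymphatic markers 0 passed over all genes (list camera adjusted p = 0.945). PDPN alone, podoplanin, passed when adjusted over the list alone, at 4.18 ± 1.02 in control and 9.52 ± 2.34 in IUGR. It was highest in IUGR replicates 2 and 4, at 11.26 and 11.60, where KRT18, WT1 and MSLN were also highest. In IUGR replicates 1 and 3 it was lower but still above every control. PROX1, RELN and STAB2 of this list lay below the olfactory receptor level of 3.44 on every array. Whether the higher PDPN reflects lymphatic cells was not tested. Of 14 leukocyte markers 0 passed either way (camera adjusted p = 0.945), among them LAPTM5, at -3.54 ± 1.53 (SE).

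**Figure D2:**
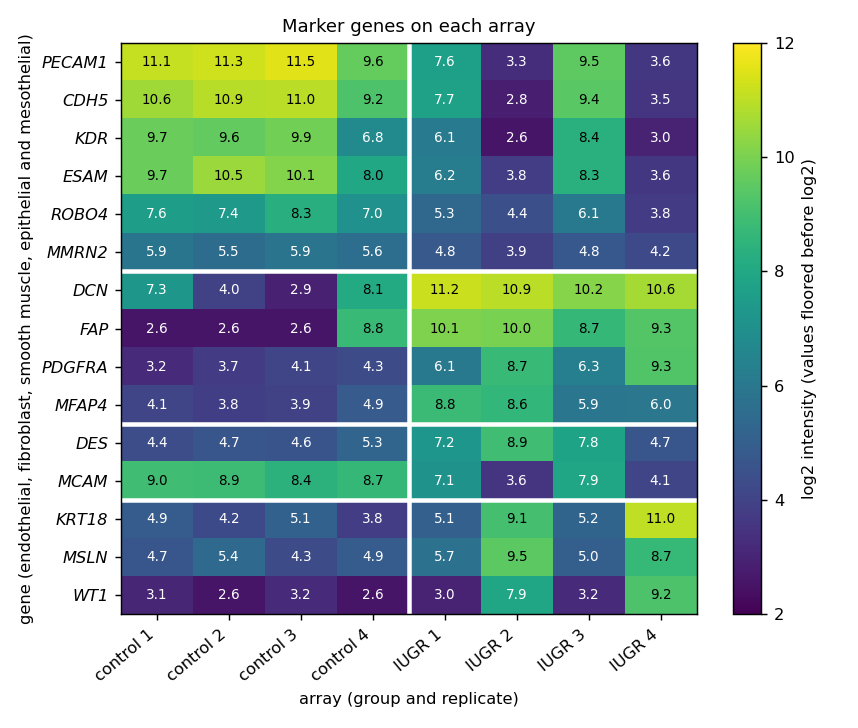
Log2 intensity (colour and printed value) of marker genes (vertical) on each of the 8 arrays (horizontal). White lines part the endothelial, fibroblast, smooth muscle, and epithelial and mesothelial genes, and the control from the IUGR arrays. PECAM1 runs from 11.5 in control replicate 3 down to 3.3 in IUGR replicate 2, and FAP is at the floor in control replicates 1 to 3.

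Arterial and Notch genes had lower values in IUGR cultures for 11 of 17 members. CXCR4, a chemokine receptor, was 9.65 ± 1.07 in control and 5.06 ± 1.52 in IUGR, NRP1, a VEGF co-receptor, was 10.38 ± 0.95 and 6.00 ± 1.73, and the endothelial Notch receptor gene NOTCH4 was 6.45 ± 0.71 and 4.54 ± 0.30. The kinase gene BMX was 7.29 ± 1.99 and 2.87 ± 0.49. Over all genes no member passed, and 8 lower and 1 higher passed when adjusted over the list alone. The list shifted lower in camera (adjusted p = 0.00444), but not with an estimated correlation (adjusted p = 0.598 with an estimated correlation), not with passage as a covariate (adjusted p = 0.475), and not without control replicate 4 and IUGR replicates 2 and 4 (0.139). The scores of this list, like those of the endothelial markers, were lowest in IUGR replicates 2 and 4. In camera with the preset correlation the list still passed as lower with the endothelial score as a covariate (adjusted p = 0.0294). It also passed as lower without IUGR replicates 2 and 4 (adjusted p = 0.0191).

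Angiogenic ligands and receptors went both ways. The growth factor HGF was at the floor of 2.56 in all 4 control arrays and 5.06 ± 0.80 in IUGR cultures. SEMA3A, a guidance factor that binds neuropilin, was 3.18 ± 1.25 and 7.33 ± 0.56, with control replicate 4 at 5.06. Of 35 members 0 passed over all genes, and 3 higher and 4 lower passed when adjusted over the list alone (camera adjusted p = 0.894). Among 29 vascular tone genes, EDNRA was the 1 call over all genes, and 3 higher members passed when adjusted over the list alone (camera adjusted p = 0.945). PTGES and PTGS2, enzymes of prostaglandin synthesis, were 4.68 ± 0.39 and 3.50 ± 1.81 in control and 7.64 ± 0.80 and 7.82 ± 1.03 in IUGR. EDN1, the endothelin-1 gene, differed by -2.37 ± 0.66 (SE).

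Hypoxia genes had higher values in IUGR cultures for 22 of 30 members. VEGFA, the leading angiogenic growth factor, was 7.26 ± 0.62 in control and 9.63 ± 0.97 in IUGR, and PDK1, a kinase that restrains pyruvate entry into mitochondria, was 6.04 ± 0.21 and 7.07 ± 0.48. ENO1, a glycolytic enzyme, differed by 0.55 ± 0.14 (SE) and BNIP3, a mitophagy gene, by 0.74 ± 0.20 (SE). No member passed over all genes, and 9 higher and 1 lower passed when adjusted over the list alone. Camera gave an adjusted p of 0.00444, and an adjusted p = 0.598 with an estimated correlation. The call ended with passage as a covariate (adjusted p = 0.171), with the endothelial score as a covariate (adjusted p = 0.139), and without control replicate 4 and IUGR replicates 2 and 4 (0.118). List scores did not overlap between the groups (exact permutation p = 0.0286, or 0.196 adjusted over the 24 lists). They were 0.36 and 0.35 in IUGR replicates 2 and 4, the arrays with the lowest endothelial scores, and 0.10 and 0.05 in IUGR replicates 1 and 3, against -0.04 in the nearest control.

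Antioxidant genes had higher values in IUGR for 22 of 29 members. SRXN1, sulfiredoxin, was 6.10 ± 0.48 in control and 7.42 ± 0.12 in IUGR cultures, and the metallothionein genes MT1E and MT2A were 7.30 ± 0.64 and 6.77 ± 0.87 in control and 9.12 ± 0.54 and 9.01 ± 0.65 in IUGR. No member passed over all genes, and 7 higher and 3 lower passed when adjusted over the list alone. The list's camera adjusted p was 0.00639 (adjusted p = 0.598 with an estimated correlation). Of 30 unfolded protein and amino acid response genes 27 had higher group means. The list scores were 0.81 and 0.29 in IUGR replicates 1 and 3. In IUGR replicates 2 and 4 they were -0.02 and -0.17, within the control range of -0.46 to -0.003 (exact permutation p = 0.143). The serine synthesis gene PHGDH differed by 1.35 ± 0.36 (SE), SHMT2 of the folate cycle by 0.82 ± 0.28 (SE), the cystine transporter gene SLC7A11 by 2.42 ± 0.89 (SE) and the chaperone gene HSP90B1 by 0.34 ± 0.14 (SE). The groups overlapped for SHMT2, SLC7A11 and HSP90B1. No member passed over all genes or when adjusted over the list alone, while the list's camera adjusted p was 0.00444 (adjusted p = 0.848 with an estimated correlation). Both lists turned lower, without a call, with passage as a covariate (adjusted p = 0.571 for antioxidant genes and 0.171 for the unfolded protein list). The first call also ended with the endothelial score as a covariate (adjusted p = 0.118), without IUGR replicate 4 (0.0864), and without control replicate 4 and IUGR replicates 2 and 4 (0.0653), and the second without IUGR replicate 1 (adjusted p = 0.193). Of 25 heat shock genes 0 passed either way (camera adjusted p = 0.334).

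NF-kB pathway components had lower values in IUGR cultures for 24 of 36 members. CD40, a receptor that activates NF-kB, was 7.93 ± 0.74 in control and 4.50 ± 1.06 in IUGR, REL, an NF-kB subunit, was 6.68 ± 0.40 and 5.02 ± 0.51, and the adaptor gene BCL10 was 8.12 ± 0.45 and 7.01 ± 0.31. IRAK4, a kinase of the same pathway, was higher, at 6.76 ± 0.24 and 7.69 ± 0.32. The subunit genes RELA and NFKB1 differed by -0.32 ± 0.12 (SE) and -0.74 ± 0.34 (SE). No member passed over all genes (9 lower and 2 higher at an unadjusted p under 0.05), and 3 lower and 1 higher passed when adjusted over the list alone. The list did not pass in camera (adjusted p = 0.108, and adjusted p = 0.848 with an estimated correlation), though it did without control replicate 4 (adjusted p = 0.0138, and adjusted p = 0.409 with an estimated correlation). The study is known to have followed NF-kB in these cells, so the list and its count are not independent evidence of a direction.

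NF-kB target and adhesion genes split, with 16 of 35 higher and 19 lower in value. F3 was the 1 call over all genes, and 4 higher and 1 lower member passed when adjusted over the list alone. The cytokine genes IL1A and LIF were 3.44 ± 1.76 and 4.42 ± 0.20 in control and 7.45 ± 0.64 and 7.17 ± 1.22 in IUGR cultures, and TNFAIP2 was 5.57 ± 0.32 and 4.35 ± 0.43. The adhesion gene ICAM1 was 7.10 ± 1.06 and 7.44 ± 0.91. Camera gave the list an adjusted p of 0.894.

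**Figure D3:**
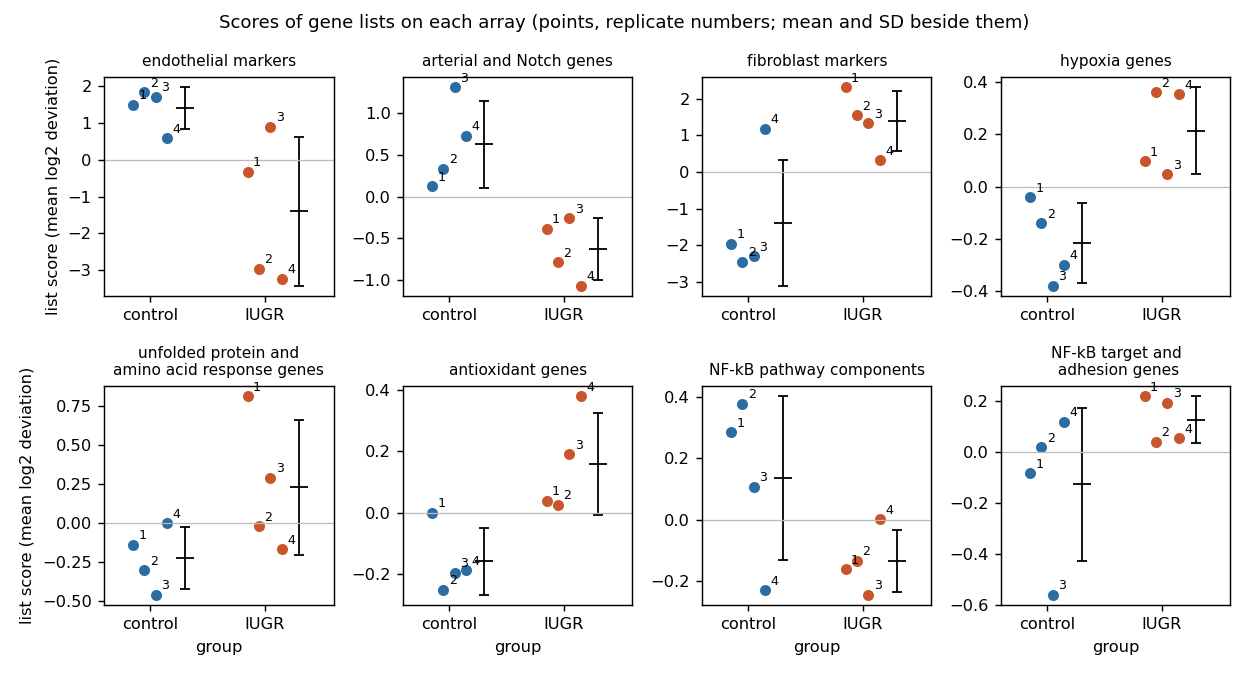
Score of each array (points with replicate numbers, vertical, in log2 units) for 8 gene lists in control (blue) and IUGR (orange) cultures, with the group mean and SD (n = 4) beside the points. Endothelial scores are 0.58 in control replicate 4, 0.90 in IUGR replicate 3 and -2.95 and -3.23 in IUGR replicates 2 and 4.

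Signalling and matrix genes gave no list call. Of 44 TGF-beta and BMP signalling genes, 0 passed over all genes and 4 higher members passed when adjusted over the list alone (camera adjusted p = 0.334). Without IUGR replicate 4 the list passed (adjusted p = 0.0401), but not with an estimated correlation (adjusted p = 0.622 with an estimated correlation). FST, follistatin, was 4.31 ± 0.68 in control and 7.79 ± 0.96 in IUGR cultures, the matrix gene TGFBI was 3.77 ± 0.81 and 8.38 ± 1.65, and the receptor gene BMPR1A was 3.37 ± 1.62 and 7.14 ± 0.46. Of 43 extracellular matrix genes 0 passed either way (camera adjusted p = 0.945), with TIMP1 at 2.24 ± 0.50 (SE) and SPARCL1 at -4.68 ± 1.29 (SE). Of 30 insulin and IGF axis genes 0 passed over all genes and 3 higher members passed when adjusted over the list alone (camera adjusted p = 0.441). IRS1, an insulin receptor substrate, was 4.27 ± 0.35 and 5.57 ± 0.37, and FOXO1, a transcription factor that insulin restrains, was 8.86 ± 0.36 and 7.95 ± 0.39.

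Of 43 interferon response genes 0 passed over all genes, and CMPK2 and GBP5 passed when adjusted over the list alone (camera adjusted p = 0.334). Without IUGR replicate 4 this list passed as lower (adjusted p = 0.0401, and adjusted p = 0.622 with an estimated correlation). CMPK2 was 8.43 ± 0.72 and 5.08 ± 0.89, and GBP5 was 6.56 ± 0.71 and 4.01 ± 0.55. No member passed either way among 47 cell cycle genes (camera adjusted p = 0.334), 45 oxidative phosphorylation genes (0.894), 27 cholesterol synthesis genes (0.894) and 18 imprinted genes (0.894). The cell cycle genes passed as lower without control replicate 4 (adjusted p = 0.00641), without IUGR replicate 3 (0.0261) and with passage as a covariate (4.107e-04), and the oxidative phosphorylation genes with passage as a covariate (1.113e-07). With an estimated correlation these calls ended, at an adjusted p of 0.848, 0.922 and 0.821 for cell cycle genes and 0.821 for oxidative phosphorylation genes. The direction of the cell cycle genes turned to higher, without a call, when control replicate 1 or IUGR replicate 1 was left out (camera adjusted p = 0.729 and 0.410). Within each group passage differs in 1 array alone, control replicate 1 and IUGR replicate 2, on which the passage term rests. None of the 9 sex-linked check genes was measured.

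The direction of some lists depended on how their members were summarised. The median and mean differences were -0.03 and 0.52 for venous and lymphatic markers, -0.03 and 0.25 for NF-kB targets, -0.07 and 0.04 for vascular tone genes, and -0.07 and 0.01 for extracellular matrix genes. Camera put the first pair of lists higher and the other pair lower. Medians of TGF-beta and cholesterol synthesis genes were also just below 0 with means of 0.49 and 0.11. Over all 24 lists camera called 6 with the preset correlation and 0 with an estimated correlation, and fry called 0 by its one-way p, which tests whether the genes of a list move, on balance, in 1 direction. By fry's mixed p, which tests whether they change in either direction and compares them with no other genes, 16 of the 24 passed, with the smallest adjusted p for vascular tone genes (5.057e-05), NF-kB targets (2.946e-04), hypoxia genes (2.946e-04) and antioxidant genes (4.300e-04).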

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

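Apart from Dixon's test and the permutation test of the endothelial score, the tests in this part were chosen after the results were seen. In 17 of 201 groups of 4 arrays, 1 array passed Dixon's test, and chance flags about 1 in 20 groups. In 5 groups (FAP, IL1A, SEMA3A, BMPR1A and CASC1 in control) the other 3 arrays tie at the floor, which fixes the outcome whatever the value of the array. Of the other 196 groups 12 passed, with 9.8 expected by chance, so the number of such groups is close to chance. Control replicate 4 was the array in 9 of the 12, although the values of 1 array are not independent of each other.

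Control replicate 4 scored 1.18 on the fibroblast markers (other controls -2.45 to -1.96) and 0.0549 on the venous and lymphatic markers (-0.38 to -0.35). Its principal component scores were 2.56 on the first (-59.8 to -56.4) and -49.0 on the second (11.5 to 18.6). FAP was 8.76, IL1A 6.08, SEMA3A 5.06 and BMPR1A 5.79 in this array and at the floor of 2.56 in the other controls. PTGS2 was 6.22, PDPN 5.71 and PHACTR1 3.77, above the other controls, and KDR was 6.80 and TAL1 5.25, below them. CASC1 was 2.64 in control replicate 3, just above the floor at which the other controls lay, TANC1 was 7.04 in IUGR replicate 1, TAL1 was 5.69 in IUGR replicate 3, and the TGF-beta and BMP score was -0.34 in IUGR replicate 4.

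The place of control replicate 4 among IUGR replicates 1 and 3 was weighed first. Fibroblast-like or smooth muscle-like cells in this culture are a candidate explanation: 18 of 36 such markers lay at least 2 log2 units above control replicates 1 to 3, against at most 1 when each of those was set against the other 2. Of the 36, 27 were above background in all of control replicates 1 to 3. An exchange with an IUGR array was not excluded: IUGR replicate 3 correlated with control replicates 1 to 3 at a mean of 0.9239 (0.914 to 0.934), about as control replicate 4 did (mean 0.9187, 0.917 to 0.922), and kept a higher endothelial score (0.90 against 0.58). IUGR replicate 3 was itself closest to IUGR replicate 1 (0.9576) and control replicate 4 (0.9548), and its fibroblast score was 1.33 against 1.18. Exchanging their labels would thus still leave a control array apart from control replicates 1 to 3. A wrong label on this array alone cannot be told apart from a mixed culture, as its highest correlation with an IUGR array was 0.9574 and with another control 0.9221.

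Endothelial markers near background in IUGR replicates 2 and 4 were weighed next. Cells of another type in place of endothelial cells are a candidate explanation. In both arrays 5 epithelial and mesothelial markers (KRT18, WT1 and MSLN, with KRT8 and CDH1 named after their values were seen) lay at least 2 log2 units above all other arrays, against 0 in any other of the 28 pairs. KRT8 was 11.67 and 12.22 in these arrays, and at most 3.79 elsewhere. Of the 15 markers of the list, 9 were above background in all of control replicates 1 to 3, and no sort that would remove such cells is given in the sources used here.

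The lower endothelial markers in IUGR cultures as a group were weighed last. The score differed by -2.81 between the groups (exact permutation p = 0.0571). Outgrowth of other cells with rising passage would lower the scores of the controls, which had the later passages, so the sign went against it. As the permutation p was not under 0.05, the test did not exclude such outgrowth. The groups shared 0 passages, so a change with passage in either direction cannot be told apart from the effect of growth restriction or of hyperthermia. With passage as a covariate the list still passed as lower in camera (adjusted p = 1.637e-06, and 0.821 with an estimated correlation), but within each group that term rests on 1 array. A change of the endothelial cells themselves in growth restriction also stays open, but the 4 IUGR arrays did not change alike. While 3 of them lay below every control score, IUGR replicate 3 (0.90) lay above control replicate 4 (0.58). Among the 3, IUGR replicates 2 and 4 also carried the epithelial and mesothelial markers, so the count does not speak for this explanation.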

How the results depend on the processing

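Leaving out IUGR replicates 2 and 4, leaving out these and control replicate 4, the endothelial score as a covariate the olfactory receptor background and the estimated correlation for calls gained in a setting or kept with passage were tried after the data were seen, and where no reason is given the cause was not tested. Each of the 10 called genes was called in 6 to 9 of 23 alternatives. Among these, the random block (consensus correlation 0.0016) and the mean of rows per gene (5 rows merged) nearly repeat the main fit. Each called the same 10 genes, so they add little to that count. Signal over background limits the dim genes, whose differences are understated at the floor.

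The 0 rows and 10 genes became 55 and 55 with rows above the median by mean, 61 and 61 with log2(value + 1), 1 and 1 with a trended prior, 20 and 74 with array weights, 122 and 120 above the olfactory receptor background (fewer genes tested), 304 and 325 without control 4, IUGR 2 and IUGR 4, 43 and 195 at an adjusted p under 0.10, and 1530 and 1540 at an unadjusted p with a fold of 1.5. Genes numbered 19 after quantile normalization, 6 with a log2 fold change of at least 1, and 0 after median centring, with log2(value + 32), a robust prior, passage or the endothelial score as a covariate, and without IUGR replicates 2 and 4. In limma's unadjusted test 1238 genes had a p under 0.05 with passage and 1105 with the endothelial score as a covariate. Leaving out 1 array gave 0 to 340 rows and 0 to 369 genes, the highest without control replicate 4.

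The 6 list calls became 0 with an estimated correlation and 0 with fry. Adjusted p values with an estimated correlation were 0.667 for endothelial markers, 0.848 for the unfolded protein list and 0.598 for arterial, fibroblast, hypoxia and antioxidant genes. With fry they were 0.158 for hypoxia genes, 0.420 for the unfolded protein list and 0.171 for the other 4. With passage as a covariate endothelial (1.637e-06) and fibroblast markers (0.00892) still passed, but not with an estimated correlation in that setting (0.821 for each). The other adjusted p values with passage were 0.475 for arterial and 0.171 for hypoxia genes, and the unfolded protein list (0.171) and antioxidant genes (0.571) reversed. With the endothelial score arterial genes (0.0294) and fibroblast markers (9.496e-05) still passed in camera with the preset correlation. The adjusted p values with that score were 0.320 for endothelial, 0.139 for hypoxia and 0.118 for antioxidant genes, of which the first is fixed by construction. Without control 4, IUGR 2 and IUGR 4 they were 0.139 for arterial, 0.118 for hypoxia and 0.0653 for antioxidant genes. Leaving out 1 array gave 2.295e-04 to 0.193 for the unfolded protein list (highest without IUGR replicate 1) and 3.223e-04 to 0.0864 for antioxidant genes (highest without IUGR replicate 4).

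NF-kB pathway components passed as lower with rows above the median (0.0308), with array weights (0.0302) and without control 4, IUGR 2 and IUGR 4 (0.00362), and leaving out 1 array gave 0.0138 (control replicate 4) to 0.273. Extracellular matrix genes reversed to higher without control 4, IUGR 2 and IUGR 4 (0.00262) and with the endothelial score (0.0465). Other lists without a call gained one: without control 4, IUGR 2 and IUGR 4 smooth muscle markers (5.104e-06) and TGF-beta genes (0.00263) passed as higher and cell cycle (0.00263) and interferon genes (0.00263) as lower. Without IUGR replicates 2 and 4 smooth muscle markers (0.0470) and TGF-beta genes (0.0191) passed as higher and interferon genes (0.0191) as lower. With the endothelial score TGF-beta genes (0.0105) passed as higher and interferon genes (0.00814) as lower. Over all settings 23 list calls were gained, those of NF-kB and extracellular matrix genes included, and 0 of them passed in limma's camera with an estimated correlation in the same setting (adjusted p = 0.388 to 0.922). The first component's group difference of 85.7 was 77.9 without IUGR replicates 2 and 4 (exact permutation p = 0.133) and 101.5 without these and control replicate 4 (0.10, the smallest p that 3 against 2 arrays allow), and 78.4 to 100.7 without 1 array. A sign turned in 60 of 622 list values, in 15 of 24 lists, the 4 reversals included, and in 32 of 1706 gene values, in 14 of 75 genes; a turn was called a reversal only where a call stood on either side.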

Other observations

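The tests of other splits of the arrays were chosen after the results were seen. Of the 35 splits of the 8 arrays into 4 and 4, 2 called at least as many genes as the real split, the real one included. Chance therefore cannot be excluded for the 10 genes. The highest other split called 59 genes, several times the real count, which points to a structure of the samples. It set control replicates 1 to 3 with IUGR replicate 4 against the rest. For rows the real split called 0, a count that all 35 splits reach by construction, so the splits decide nothing there, and the highest other called 56. For gene lists 19 of the 35 splits, the real one included, called at least the real 6, with a highest other of 11. Chance cannot be excluded there either.

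Without control replicate 4 the real grouping called 369 genes, and the highest other of the 35 splits of those 7 arrays called 9, but the array was left out after its values were seen and these splits do not repeat that choice. When each of the 35 splits of the 8 arrays was likewise given the removal that called most genes, 2 reached as many, the real one included, and the highest other called 388, so chance cannot be excluded for that count either. That other split joined IUGR replicate 4 to control replicates 1 to 3 and left IUGR replicate 4 out. The splits with IUGR replicate 3, 2 or 1 in its place called 272, 184 and 139, each with that array left out, and every split without control replicates 1 to 3 on 1 side called at most 12. The counts point to a structure of the samples in which control replicates 1 to 3 stand apart from the other 5 arrays.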
